A study of Homo sapiens with 11 samples.

How the data were processed

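Lymphocyte RNA from patients with CLL was profiled for miRNAs in 11 pools of 4 patients each: 2 blood pools at each of 5 time points and 1 marrow pool. Per the labels' protocols, CLL cells were isolated on a Ficoll gradient, frozen, thawed into Trizol, and their RNA was purified with a miRNA kit. No sort for B cells is named there. The isolation text names peripheral blood for all 11 pools, the marrow pool included, whose title and tissue label say bone marrow, so the comparison with marrow rests on those. Groups and pool numbers were taken from the sample titles. The labels give an array-type profiling of non-coding RNA. The platform, the background correction, the normalization method, the log base and any filter behind the list of 276 miRNAs are not given in the sources used here.

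The deposited values were taken as log2 values, already normalized between pools by the authors. The normalization was read from the values: every pool has the same maximum (15.88), the medians lie between 5.44 and 5.47, and 64.1% to 72.1% of the miRNAs in a pool share their value with another one. Such a shared distribution is that of a quantile-type normalization, which hides any change that moves all miRNAs alike. Base 2 was assumed, not stated. The number of distinct levels in a pool does not establish it, since the normalization sets those levels: between 4.5 and 5.5 a pool holds 17 to 25 of them, where whole counts would give up to 23 in base 2 and 154 with a natural log. Every fold printed here rests on that assumption. No counts are given, so the depth per pool is unknown, and neither intervals nor floors from counting were computed.

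No scaling was added. Background was set in each pool at the 90th percentile of 7 C19MC miRNAs, a placental cluster that lymphocytes are taken to lack, and a miRNA was tested if it exceeded background in at least 2 of the 11 pools, which left 124. The files' miRNA names are older ones, often without the arm. 264 of the 276 matched a gene symbol of the GRCh38.p14 annotation, which was used only for names and neighbouring genes, and no coordinates are given because no build is named for the files. 3 of the names cover more than 1 mature miRNA.

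Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values, with 6 groups over all 11 pools, no covariate and 5 residual degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg over the miRNAs tested in each comparison, with a threshold of 0.05. The comparisons were each treated time point against blood before treatment, a moderated F test over those 4, the mean of the treated groups against before, late (8 and 29 days) against early (2 and 24 hours), and marrow against blood before treatment. With 2 pools on each side an exact permutation test cannot go below p = 0.333, so single time points rest on the spread that limma pools over all groups. The median SE of a difference was 0.24 log2 for a single time point, 0.17 for late against early and 0.29 for marrow.

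The comparisons, tests, filter, alternatives, miRNA lists and the rule for naming miRNAs were fixed before the data were examined. By that rule, where fewer than 10 miRNAs passed a comparison, the 6 with the smallest unadjusted p in each direction were named as not passing, together with members of the lists. The lists were the miR-29 family, the miR-15 and miR-16 family, the miR-17-92 and paralogous clusters, let-7 and miR-98, the miR-181 family, miRNAs induced by NF-kB or the B cell receptor, miRNAs abundant in B cells and CLL, p53-responsive miRNAs, the 14q32 and C19MC clusters, a hypoxia list, and markers of myeloid, erythroid, platelet, T and NK, stromal and endothelial, epithelial and progenitor cells. A further list holds miRNAs recalled from published work on these samples. Its member miR-181b was not used here because the table used here does not list it. Several miRNAs sit on more than 1 list. Lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with an estimated one), adjusted over 13 lists and 7 contrasts. fry served as an alternative. The limma p-values of list members were also adjusted over each list alone, within 1 contrast. These are not adjusted over the lists or contrasts, and a miRNA on more than 1 list is counted in each.

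The pool numbers were taken to pair the samples, as read from the data and not from a statement about which patients are in which pool. Over the 124 tested miRNAs, the difference of pool 1 and pool 2 correlated between every 2 time points (Pearson 0.32 to 0.84, Spearman 0.17 to 0.65, 10 pairs, across miRNAs, which are not independent replicates). Without miR-590-5p and miR-148b the Pearson values ran from -0.02 to 0.70 and the Spearman values from 0.12 to 0.63. Each comparison was therefore also read with pool number as a block.

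Alternatives were other scalings between pools, other variance models of limma, other filters on low values, pool number as a block, fewer samples in the fit and leaving out each pool in turn. The fits were tested on simulated data drawn 50 times with 124 miRNAs, of which 24 were changed. Each miRNA kept its mean, its residual SD and 1 pool effect at all time points, with noise drawn independently for each miRNA and pool. The shares recovered hold for that setting and may differ in the real data. For late against early, limma recovered 35.5%, 79.5% and 92.2% of changes of 0.5, 1 and 2 log2. For 29 days against before treatment the shares were 12.8%, 50.5% and 86.5%, and for marrow against blood 3.25%, 39.2% and 77.8%. False calls per simulation were 0.28, 0.2 and 0.14 in these 3 comparisons. With pool number as a block they were 0.92, 0.78 and 0.68, with more of the changes recovered. camera found a list shifted by 0.5 log2 late against early in 50 of 50 simulations, and an unshifted one in 2. These counts used the unadjusted p of 1 list and noise drawn independently for each miRNA. They do not show how often such a shift would pass after adjustment over 13 lists and 7 contrasts.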

Results

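Levels of microRNAs (miRNAs), short RNAs that lower the stability and translation of messenger RNAs, were measured in lymphocytes from patients with chronic lymphocytic leukaemia (CLL), a malignancy of mature B cells. Samples were taken before and during treatment with ibrutinib, an oral inhibitor of BTK, the kinase that carries signals from the B cell receptor, at 420 mg per day. RNA from 4 patients was combined in each of 11 pools. Blood lymphocytes gave 2 pools (8 patients) at each of 5 points: before treatment and after 2 hours, 24 hours, 8 days and 29 days. Marrow lymphocytes gave 1 pool, taken before treatment. Because each value belongs to a pool, the p-values below measure the spread between pools of 4 patients and not between persons. Pools of one number were more alike across groups (median r = 0.981) than pools of one group (0.961). Pools of one number may therefore hold the same patients or share an effect of the measurement, while the main fits take all pools as independent. The values were taken as log2 and come without counts, so the depth behind them is unknown, and the number of pools limits the precision.

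Several miRNAs known from mature B cells lay far above background in these pools. Their levels do not rank their abundance, since probes for different miRNAs can respond differently. miR-150, which marks mature lymphocytes, had the highest level in every pool (15.88), a ceiling set by the normalization, so no difference in it could be seen. miR-16, whose locus is often deleted in CLL, averaged 15.05 over the 11 pools, miR-26a 14.56, miR-142-3p 14.27 and miR-21 13.09. miR-155, induced by B cell receptor and NF-kB signalling, averaged 11.16. Background, read from miRNAs of the placental C19MC cluster, lay between 5.72 and 6.40. Of the 276 miRNAs listed, 140 exceeded it in no pool, 73 exceeded it in all 11 pools, and the 124 that exceeded it in at least 2 pools were tested.

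The first comparison asked which miRNAs differ 2 hours after the first dose. miR-331-3p was 1.65-fold lower than before treatment (-0.72 ± 0.24 log2, SE, n = 2 and 2 pools), and miR-362-3p was 1.32-fold lower (-0.40 ± 0.13). The level of miR-362-3p at 2 hours lay near background. miR-146b-5p, an NF-kB-induced miRNA that restrains the same pathway, averaged 5.72 against 6.43 before treatment (-0.71 ± 0.33), both near background. miR-22 averaged 7.38 against 6.99 (0.39 ± 0.19), and miR-548a-5p was 1.46-fold higher (0.55 ± 0.19; 0.32 without pool 2 of 2 hours). Among the other miRNAs with the smallest p, let-7c, miR-496, miR-660 and miR-503 were higher, and let-7g, miR-142-3p and miR-19b were lower. None of these differences passed the test. limma called 0 of 124 miRNAs, with 5 at an unadjusted p under 0.05 where chance gives 6.2, and 0 again with pool number as a block (10 unadjusted). The smallest adjusted p was 0.983.

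At 24 hours miR-146b-5p had the largest difference among the 6 miRNAs with the smallest p in each direction. It was at 5.95 against 6.43 (-0.47 ± 0.33 log2, SE, n = 2 and 2 pools). The level of 5.95 lay at the background of the 24 hour pools. miR-1246 was 1.32-fold higher (0.40 ± 0.18). miR-301a was lower (-0.46 ± 0.25), at an average of 5.61 that lay under the background of the 24 hour pools (6.01 and 5.82). miR-27a, a miRNA of myeloid cells, was 1.38-fold lower (-0.46 ± 0.29). Without pool 1 of 24 hours the differences of miR-146b-5p, miR-1246 and miR-301a were -0.29, 0.20 and -0.14. miR-660, let-7c, miR-130b, miR-29c and miR-222 were also among the 6 highest-ranked increases, and miR-1537, miR-592 and miR-548g among the decreases. limma called 0 of 124 miRNAs, with 0 at an unadjusted p under 0.05, and 0 with pool number as a block (1 unadjusted). Every adjusted p was 1.

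After 8 days miR-155 was 1.48-fold lower than before treatment, at 10.86 ± 0.22 (SD, n = 2 pools) against 11.43 in both pools before treatment (-0.57 ± 0.14 log2, SE). miR-29c, of a family that targets MCL1 and TCL1A, was 1.45-fold higher (0.54 ± 0.18). The red cell miRNA miR-144 was 2.45-fold higher on average (1.30 ± 0.74), but the difference was 2.59 in pool 1 and 0 in pool 2. miR-148a was 1.51-fold lower (-0.59 ± 0.29; -0.30 without pool 1 of 8 days) and miR-23a, a myeloid miRNA, 1.37-fold lower (-0.46 ± 0.20). miR-520e, miR-194, miR-503 and miR-140-3p were among the highest-ranked increases, and miR-1537, miR-484 and miR-106b among the decreases. limma called 0 of 124 miRNAs, with 2 at an unadjusted p under 0.05, and 0 with pool number as a block (8 unadjusted). The adjusted p of miR-155 was 0.667 over all miRNAs tested and 0.0269 adjusted over the list alone, the list being 5 tested miRNAs induced by NF-kB or the B cell receptor. It did not pass in the B cell and CLL list (0.0753), and the pass ended without pool 1 or pool 2 before treatment or pool 1 of 8 days.

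After 29 days miR-155 was 1.73-fold lower than before treatment, at 10.64 ± 0.10 (SD, n = 2 pools) against 11.43 (-0.79 ± 0.14 log2, SE). The difference was -0.86 in pool 1 and -0.72 in pool 2. miR-29c was 1.66-fold higher (0.73 ± 0.18) and miR-29a 1.38-fold higher (0.47 ± 0.15; 0.28 without pool 2 of 29 days). miR-331-3p was 1.99-fold lower (-0.996 ± 0.24), and its level of 6.03 was close to background. miR-126, a miRNA of endothelial cells, platelets and progenitors, was 2.05-fold higher (1.04 ± 0.41).

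Other miRNAs ranked highest at 29 days were miR-101 (0.34 ± 0.12 log2, SE), miR-19a (0.27 ± 0.11), let-7f (-0.38 ± 0.13), miR-194 (-0.53 ± 0.21), miR-148a (-0.70 ± 0.29) and miR-548g (-0.43 ± 0.19). The difference of miR-148a was -0.30 without pool 1 of 29 days and -1.10 without pool 2, and that of miR-194 was -0.27 without pool 2 before treatment. miR-520e was also higher (0.93 ± 0.33), but it belongs to the placental cluster that sets the background. limma called 0 of 124 miRNAs, with 11 at an unadjusted p under 0.05 (6 higher, 5 lower), and 0 with pool number as a block (19 unadjusted). The smallest adjusted p was that of miR-155, 0.119. miR-155 alone passed under 2 alternatives, a robust variance estimate with a trend (adjusted p = 0.0497) and a test of only the miRNAs above background in all pools (0.0455), in a range of 0.0455 to 0.555 over 22 alternatives. Among 124 miRNAs, 54 (43.5%) had both pools at 29 days above or below both pools before treatment, against 27 (21.8%) at 2 hours, 18 (14.5%) at 24 hours and 29 (23.4%) at 8 days. Chance gives 33.3% for pools that can be freely exchanged, which the differences between pool numbers do not allow here.

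Taking the 4 treated time points together, miR-155 averaged 11.07 ± 0.37 (SD, n = 8 pools) against 11.43 before treatment (-0.36 ± 0.11 log2, SE). miR-331-3p was 1.5-fold lower (-0.59 ± 0.19) and miR-29c 1.30-fold higher (0.38 ± 0.14). miR-503, miR-660, miR-1246, let-7c and miR-29a followed among the increases, and miR-1537, miR-106b, miR-362-3p and miR-27a among the decreases. limma called 0 of 124 miRNAs for this mean, with 3 at an unadjusted p under 0.05, and 0 with pool number as a block (5 unadjusted). The F test for a difference at any time point also called 0, with 7 at an unadjusted p under 0.05 and 0 with the block (21 unadjusted). It ranked miR-155 first (adjusted p = 0.298), then miR-29c, miR-331-3p, miR-101, miR-548a-5p and miR-194 (each 0.614).

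**Figure D1:**
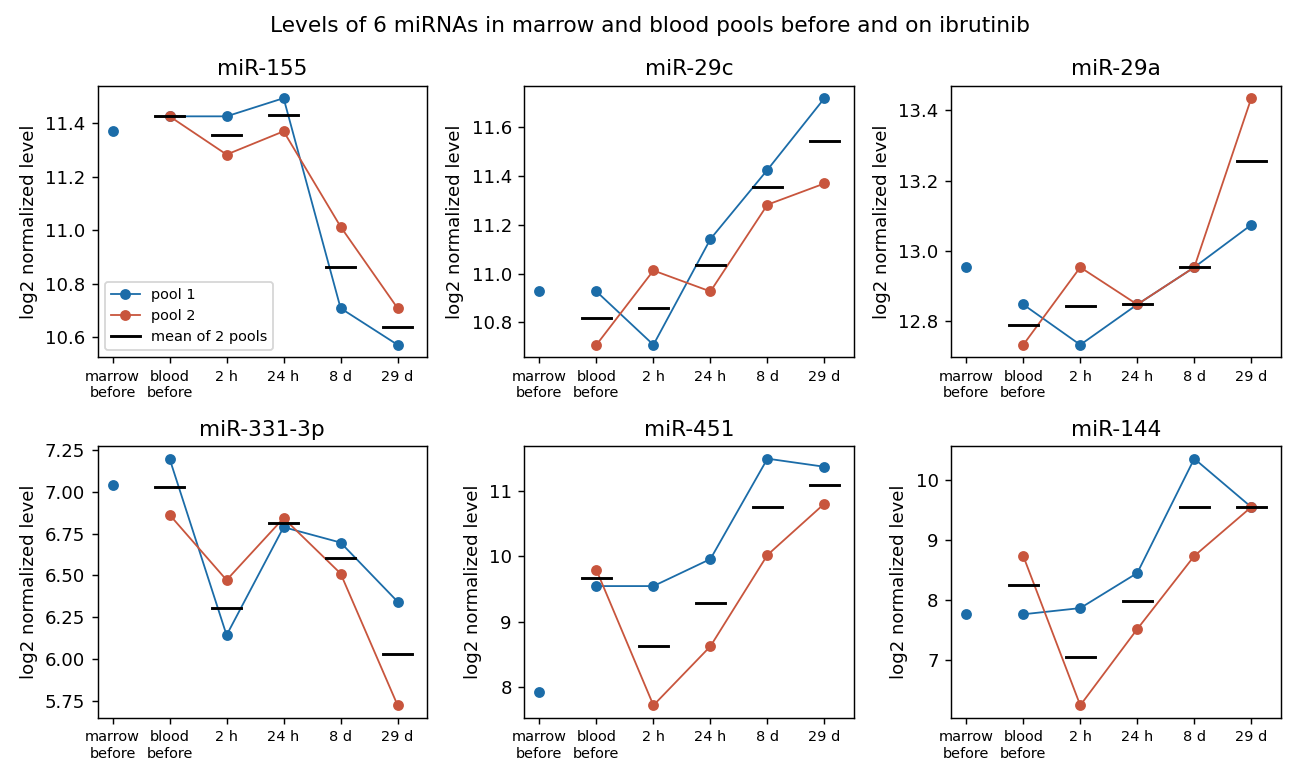
Levels of 6 miRNAs (vertical axes, log2 normalized level, each panel with its own range) in the marrow pool and the blood pools before and on ibrutinib (horizontal axes, sampling time, not to scale). Points are single pools of 4 patients, coloured lines join blood pools of one number, and black bars are means of 2 pools; miR-155 lies between 10.57 and 11.01 in the 4 pools of 8 and 29 days and between 11.28 and 11.49 in the 4 pools of 2 and 24 hours.

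The contrast of late (8 and 29 days) with early treatment (2 and 24 hours), 4 pools on each side, had the smallest median SE. A side holds 2 pool numbers at 2 time points each, so its 4 pools may not be independent. miR-155 was 1.56-fold lower late, at 10.75 ± 0.19 against 11.39 ± 0.09 (SD, n = 4 and 4 pools; -0.64 ± 0.10 log2, SE), with differences of -0.82 in pool 1 and -0.47 in pool 2. The red cell miRNAs miR-144 and miR-451 had the largest increases, 4.07-fold (2.03 ± 0.53) and 3.89-fold (1.96 ± 0.55). Part of this gap came from lower values in the early pools numbered 2, at -2.49 and -1.22 from before treatment for miR-144 at 2 and 24 hours and -2.07 and -1.17 for miR-451. miR-29c was 1.42-fold higher (0.50 ± 0.13) and miR-101 1.29-fold higher (0.37 ± 0.09). miR-187 was also higher (0.61 ± 0.20), but it averaged 5.63 at 24 hours, under the background of those pools (6.01 and 5.82). miR-148a was 1.65-fold lower (-0.72 ± 0.21).

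Near background, miR-548a-5p (-0.53 ± 0.13 log2, SE), miR-548i (-0.38 ± 0.11) and miR-496 (-0.42 ± 0.17) were lower late than early, as was let-7b, further above background (-0.32 ± 0.12; -0.21 without pool 1 of 24 hours), and the placental miR-520e was higher (0.77 ± 0.23). limma called 0 of 124 miRNAs, with 20 at an unadjusted p under 0.05 (12 higher, 8 lower), and 0 with pool number as a block (31 unadjusted). The adjusted p was 0.0524 for miR-155, 0.178 for miR-101, miR-29c and miR-144 and 0.192 for miR-451. No overlap between the 4 late and the 4 early pools was seen for 9 miRNAs, 7.26% of those tested, where chance gives 2.86% for freely exchanged pools.

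The call of miR-155 in this contrast turned on the setting. Its adjusted p ran from 0.0183 to 0.238 over 24 alternatives and passed in 5 of them, among them a fit without pool 2 of 8 days (0.0483). When the 8 treated pools were fitted as 2 groups with pool number as a block, an alternative chosen after the data were seen, limma called 4 miRNAs: miR-451 (adjusted p = 0.0246), miR-144 (0.0363), miR-155 (0.0363) and miR-148a (0.0463). With the level of the red cell miRNA miR-451 as a covariate, also chosen after the data were seen, limma called 0 (21 at an unadjusted p under 0.05). The difference was then 0.28 ± 0.38 log2 for miR-144 and -0.32 ± 0.32 for miR-148a, against -0.62 ± 0.18 for miR-155. Near background, it was -0.89 ± 0.20 for miR-496 and -0.32 ± 0.22 for miR-548a-5p.

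Before treatment, miR-93 of the miR-106b cluster was 1.43-fold higher in the marrow pool than in blood (0.51 ± 0.20 log2, SE, n = 1 and 2 pools), and miR-126 averaged 6.99 against 6.16 (0.83 ± 0.51). miR-194 was 1.76-fold lower in marrow (-0.82 ± 0.26), at a level of 4.78 that is below background. The red cell miRNA miR-451 stood at 7.93 in marrow and 9.67 in blood (-1.74 ± 0.95). miR-1308, miR-548a-5p, miR-496 and miR-374a were among the highest-ranked increases, and miR-1537, miR-490-3p, miR-296-5p, miR-590-3p and miR-185 among the decreases. limma called 0 of 124 miRNAs, with 4 at an unadjusted p under 0.05, and 0 with pool number as a block (14 unadjusted). The marrow pool has no replicate, so its spread was taken to be that of the blood pools. It is numbered 1 but was set against both blood pools, so the main fit partly mixes tissue with pool number. Against blood pool 1 alone the difference was 0.51 log2 for miR-93, 0.63 for miR-126, -0.56 for miR-194 and -1.61 for miR-451.

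Among the 13 miRNA groups tested, the miR-29 family had the smallest camera p at 29 days and late against early, without passing. Its 3 members, miR-29a, miR-29b and miR-29c, were all higher at 29 days than before treatment, with a median difference of 0.47 log2, and all were higher late than early, with a median of 0.26. Both medians are those of miR-29a. Leaving out 1 pool moved them to 0.28 to 0.55 at 29 days, the lowest without pool 2 of 29 days, and to 0.18 to 0.45 late against early, the highest without pool 2 of 2 hours and the next without pool 1 of 8 days (0.43). miR-29b differed by 0.29 ± 0.33 (SE) at 29 days and by 0.25 ± 0.23 late against early. The latter was 0.06 without pool 1 of 2 hours and 0.45 without pool 2. With miR-451 as a covariate it was 1.04 ± 0.15, without passing (adjusted p in limma 0.0613). Adjusted over the list alone, miR-29a and miR-29c rose at 29 days (smallest adjusted p = 0.0182) and miR-29c rose late against early (0.0204), while 0 members passed over all miRNAs tested. Of the 11 fits that leave out 1 pool, miR-29a passed over the list in 8 and miR-29c in 9 at 29 days, neither without pool 2 before treatment, and miR-29c in 8 late against early. camera gave the family an adjusted p of 0.196 in both contrasts, and 0.983 with an estimated correlation. MIR29A and MIR29B1, and likewise MIR29C and MIR29B2, are neighbouring genes with no annotated gene wholly between them.

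Of the 5 tested miRNAs induced by NF-kB or the B cell receptor (miR-155, miR-146a, miR-146b-5p, miR-21 and miR-22), 4 were lower at 29 days and 1 was higher, with a median difference of -0.40 log2. Adjusted over the list alone, miR-155 fell at 29 days (adjusted p = 0.00478) and late against early (0.00211), and in all 11 fits that leave out 1 pool. The median at 29 days ran from -0.65 without pool 2 before treatment to -0.16 without pool 1 before treatment in those fits. miR-21 was at 12.79 at 29 days against 13.19 before treatment (-0.40 ± 0.20, SE, n = 2 and 2 pools), and miR-22 was on the other side (0.22 ± 0.19). The difference of miR-21 was -0.16 without pool 1 before treatment, and that of miR-22 was -0.03 without pool 2 of 29 days. The group as a whole did not pass in camera (adjusted p = 0.414 at 29 days). Over all miRNAs tested, miR-155 did not pass either (adjusted p in limma 0.119 at 29 days and 0.0524 late against early).

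The miRNAs abundant in B cells and CLL cells showed no common direction. Of 14 tested members, 4 were higher and 9 lower at 29 days, with a median difference of -0.07 log2. This median was -0.18 without pool 2 before treatment and 0 without pool 1 before treatment. Adjusted over the list alone, miR-155 fell and miR-29c rose (smallest adjusted p in limma 0.0134). Of the 11 fits that leave out 1 pool, miR-155 passed over this list in 9, in neither of those without a pool before treatment, and miR-29c in 4. miR-15a, miR-15b and miR-16, of a family that targets BCL2, had a median difference of -0.04 at 29 days (0.23 without pool 1 of 29 days, where miR-16 passed over the list). In the miR-17-92 and paralogous clusters, induced by MYC, 7 of 10 tested members were lower at 29 days (median -0.14). Of 8 let-7 and miR-98 members 6 were lower (median -0.20, with a range of -0.20 to -0.07 over the fits that leave out 1 pool). The 3 tested miRNAs of the p53 response, miR-34a, miR-194 and miR-107, were all lower at 29 days (median -0.53). This median was -0.33 without pool 2 before treatment and -0.79 without pool 1 before treatment. Before treatment miR-194 and miR-107 averaged 5.60 and 5.90, where background was 5.96 in pool 1 and 5.80 in pool 2. Background was higher at 29 days (6.34 and 6.01), so both lay at or under the floor. miR-34a averaged 6.39 before treatment, above background, but its average at 29 days lay under the background of both pools. None of these groups passed in camera at 29 days, and the smallest adjusted p among them was 0.405, for the p53 list.

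The miRNAs miR-22, miR-34a and miR-146b-5p, recalled from published work on these samples, were read as a separate list, which is not independent evidence because it was chosen on these samples. At 29 days miR-34a differed from its level before treatment by -0.68 ± 0.39 log2 (SE, n = 2 and 2 pools), miR-146b-5p by -0.44 ± 0.33 and miR-22 by 0.22 ± 0.19. These values rested on single pools: miR-34a was at -0.37 without pool 2 before treatment, and without pool 1 of 29 days miR-146b-5p was at 0.07 and the list median turned from -0.44 to 0.07. The 29 day averages of miR-34a and miR-146b-5p also lay under the background of those pools (6.34 and 6.01). Adjusted over the list alone, 0 of the 3 passed at any time point, as over all miRNAs tested. In fits that leave out 1 pool, miR-146b-5p and miR-22 passed over the list at 2 hours without either pool of 29 days (smallest adjusted p in limma 0.0283), and miR-146b-5p at 29 days without pool 2 of 29 days (0.0182). The smallest list adjusted p in limma was 0.12, at 2 hours, and 0 had an unadjusted p under 0.05 there.

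No marker list of other blood cells passed camera late against early, where the smallest adjusted p among them was 0.405. Of the 4 tested erythroid miRNAs, miR-144, miR-451 and miR-96 were higher and miR-16 lower late against early, and adjusted over the list alone miR-144 and miR-451 rose (smallest adjusted p = 0.0201; median of the list 1.01 log2). Both passed in 6 of the 11 fits that leave out 1 pool, and in none without pool 1 of 8 days, pool 2 of 2 or 24 hours or either pool of 29 days. All 6 tested myeloid miRNAs, among them miR-223 (-0.34 ± 0.26 log2, SE) and miR-24 (-0.39 ± 0.16), were lower late than early (median -0.31), and 0 passed over the list alone (smallest adjusted p in limma 0.226). Without pool 1 of 2 hours the median was -0.38 and miR-23a, miR-24 and miR-27a passed over the list (0.0181), and without pool 2 of 2 hours it was -0.13 and 0 passed. miR-223 was at -0.57 and -0.11 in these fits, at -0.17 and -0.51 without pool 1 and pool 2 of 29 days, and at 0.40 ± 0.29 with miR-451 as a covariate. miR-24 was at -0.25 without pool 2 of 2 hours and at -0.04 ± 0.23 with that covariate. Of 4 platelet miRNAs 2 were higher and 2 lower, led by miR-126 (0.89 ± 0.29), which is also 1 of the 4 progenitor miRNAs (median -0.06). With miR-451 as a covariate miR-126 differed by 0.06 ± 0.34. The progenitor median ran from -0.14 to 0.07 over the fits that leave out 1 pool. Of 5 T and NK cell miRNAs, 3 were lower and 1 higher (median -0.26; 0 without pool 1 of 24 hours). In the platelet, progenitor and T and NK lists 0 members passed over the list alone. miR-126 passed over the platelet and progenitor lists without pool 1 of 24 hours (adjusted p in limma 0.0479) or pool 2 of 8 days (0.0169), and miR-222 over the T and NK list without pool 2 of 29 days (0.0294). camera called 0 of 91 tests over 13 lists and 7 contrasts, and 0 again with an estimated correlation, with fry or with pool number as a block.

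A few lists had fewer than 3 tested members and were not tested as groups. The 14q32 cluster had 1 (miR-379), the epithelial list 1 (miR-200a), the miR-181 family 1 (miR-181a, 0.04 ± 0.23 log2, SE, at 29 days), the stromal and endothelial list 2 (miR-126 and miR-21), and the placental C19MC cluster 2 (miR-518f and miR-520e). The hypoxia list (miR-210) had 0 members in the table used here.

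Pools 1 and 2 differed for several miRNAs at all blood time points. Averaged over the 5 blood time points, miR-590-5p was at 2.42 in pool 1 and 6.90 in pool 2 (-4.49 ± 1.12, SD, n = 5 time points), and miR-148b at 3.97 and 6.80 (-2.82 ± 1.55). miR-590-3p, from the other arm of the miR-590 hairpin, was at 6.97 and 6.89 (0.09 ± 0.24). The largest differences from before treatment at 24 hours and 29 days, of miR-590-5p (-0.64 ± 2.85 and 1.62 ± 2.85 log2, SE), and at 8 days, of miR-148b (1.37 ± 1.95), were smaller than their SE. miR-151-5p was lower in pool 1 (-1.58 ± 0.42) and miR-146a higher (1.11 ± 0.39). Over the 124 tested miRNAs, 29 (23.4%) differed in the same direction at all 5 time points, where random signs give 6.25%. The first principal component, with 50.4% of the variance, separated the pool numbers. The second, with 20.2%, had scores of 0.74 to 3.76 in the 4 late pools and -3.73 to -0.56 in the 4 early pools. How much single miRNAs weigh in either component was not read. miR-590-5p and miR-148b, furthest apart between the pool numbers, may carry much of the first, and miR-144 and miR-451 much of the second.

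**Figure D2:**
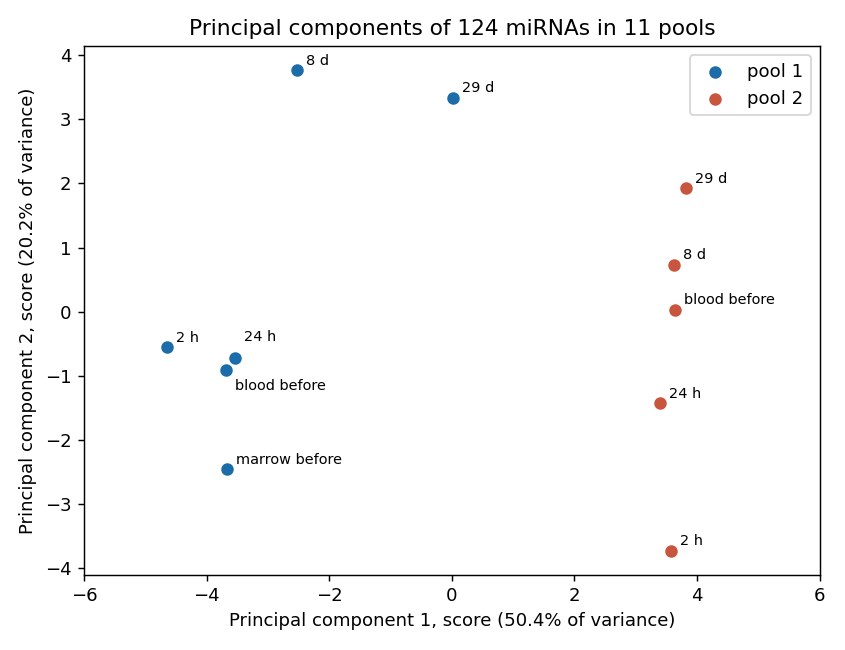
Scores of the 11 pools on the first and second principal components of the tested miRNAs (unitless scores; 50.4% and 20.2% of the variance). Each point is 1 pool, coloured by pool number and named by its sampling time; pools numbered 2 lie at scores of 3.39 to 3.82 on the first component, and pool 1 at 29 days (0.02) lies nearest to them.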

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

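Of 108 differences given for named miRNAs, 99 did not reverse under any alternative run (miR-16 late against early reached 0) and 9 did, and the list tests in camera stayed at 0 calls in all 14 of theirs. Over the fits that leave out 1 pool, these ranges crossed 0: at 24 hours -0.751 to 0.22 for miR-144, -1.044 to 0.291 for miR-451 and -3.424 to 2.142 for miR-590-5p; at 8 days -0.232 to 2.966 for miR-148b; at 29 days -0.961 to 0.073 for miR-146b-5p, -0.028 to 0.465 for miR-22, -0.034 to 0.114 for miR-181a and -1.167 to 4.399 for miR-590-5p. Late against early, miR-223 turned from -0.338 to 0.404 with miR-451 as a covariate, and the cause was not tested. The counts at 2 hours, 24 hours and 8 days, the F test, the mean of the treated groups and the marrow comparison stayed at 0 in every alternative run, 20 to 22 per comparison. For 29 days, 20 of 22 alternatives gave 0 calls, and 1 call (miR-155) appeared with trend and robust variances and with the filter for background in all pools. Late against early gave 1 call (miR-155) with trend and robust variances, with the filter for background in all pools and with a filter 1 log2 above background; both filters test fewer miRNAs (73 and 79), and the cause was not tested otherwise. Leaving out 1 pool at a time gave 0 to 1 calls late against early, the 1 being miR-155 without pool 2 of 8 days, and 0 in the other comparisons. It moved 56 of the 108 differences by over 1.5 times, 13 of 15 at 24 hours, 10 of 15 at 8 days, 11 of 20 at 29 days and 7 of 19 late against early. Of the 83 list tests with 0 members passing over the list alone, 20 had a member passing in at least 1 such fit. 3 alternatives were chosen after seeing the data. The 8 treated pools as 2 groups gave 0 calls (smallest adjusted p = 0.06), the same pools with the replicate block of pool number gave 4, and miR-451 as a covariate gave 0. Pool number as a block changed no call in the planned fits (0 in each). Another scaling of raw counts, DESeq2, edgeR and another pseudocount were not run because the values are logged and normalized, and the marrow comparison has no fit on blood pools alone. miRNAs below about 6.4 lie near background in some pools, and their differences are the least certain.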

Other observations

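The tests of this part were chosen after the results were seen, except the count of other splits of the treated pools and the tests of lists. Setting the treated time points against each other, limma called 0 of 124 miRNAs in each of the 6 pairs, with 22 at an unadjusted p under 0.05 for 29 days against 2 hours, 13 each for 8 days against 2 hours and 29 days against 24 hours, and 1 to 7 in the other pairs. miR-194, a p53-responsive miRNA at or near background, was 0.37 log2 above its level before treatment at 8 days, by 0.69 in pool 1 and 0.05 in pool 2. At 29 days it was -0.53 from that level, lower in both pools. The difference was 0.11 at 8 days without pool 1 before treatment and -0.27 at 29 days without pool 2 before treatment. The 8 and 29 day values differed by -0.90 ± 0.21 (SE, n = 2 and 2 pools), with an adjusted p of 0.493. let-7f (-0.38 ± 0.13) and miR-19a (0.39 ± 0.11) also differed between these days without passing.

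One possible cause of the lower miR-155 after 8 and 29 days is dilution of lymphocyte RNA by red cell RNA. The change of miR-155 minus the median change of the other 13 B cell and CLL miRNAs (-0.05) was -0.594. That argues against dilution as the whole cause, as far as these 13 come from lymphocytes and are free to fall. Among them, miR-150 sat at the ceiling and miR-16, also abundant in red cells, near it. Dilution as a part of the cause stays open. With miR-451 as a covariate miR-155 differed by -0.62 ± 0.18 (limma, adjusted p = 0.201), against -0.64 ± 0.10 without it. miR-451 itself differed by 1.96 late against early, so this fit cannot separate red cell RNA from time well. Whether the normalization between pools set the size of the fall of miR-155 stays open. All pools share the same values at the 25 highest ranks, so the rank there restates the level. Its rank from the top was 15 to 18 in the early pools and 21 to 25 in the late ones, with a median 7.5 places lower. A normalization that keeps the order within each pool cannot make such a drop, which argues against it as the whole cause. The method is not given, so that it kept the order is an assumption. Chance cannot be excluded over all splits. Of 35 splits of the 8 treated pools, 3, the real one counted, had at least its 17 miRNAs at an unadjusted p under 0.05. The highest other was 27, for the split by pool number, which also called 6 and points to a structure of the samples. Among the 18 splits that keep pool numbers balanced, the real one was the highest (17, next 8). It was so too with pool number as a block (26 against 11). First place among 18 cannot fall under 0.05, so this ranking does not exclude chance either. By adjusted calls without a block, another balanced split gave 1 and the real one 0. With the block the real one gave 4 and other balanced splits up to 1. A lower B cell receptor and NF-kB input under ibrutinib may lower miR-155, and a change in the mix of cells may do so as well. The marker lists bear on the mix without deciding it: late against early the 6 myeloid miRNAs had a median of -0.307 (-0.127 without pool 2 of 2 hours, -0.383 without pool 1) and the 4 erythroid ones of 1.013, with a camera adjusted p of 0.405 each. Both stay open.

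For miR-451 and miR-144, higher at 8 and 29 days than at 2 and 24 hours, the SD of their log2 difference over the 11 pools was 0.461 against 1.25 for miR-451 itself, which is consistent with a share of red cell RNA that differs between the pools. The late pools alone do not make the gap: against before treatment miR-144 differed by -1.193 and miR-451 by -1.036 at 2 hours, through pool 2 (-2.487 and -2.072), and pool 2 of 8 days differed by 0 and 0.23. MIR144 and MIR451A are neighbouring genes, so a change in their own expression would keep the ratio as well and stays open. miR-16, also abundant in red cells, was at 15.08 in most pools, near the ceiling, and decides nothing.

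miR-590-5p and miR-148b were low in the pools numbered 1. Absence of the miR-590 hairpin transcript from those patients' cells is argued against: miR-590-3p, from its other arm, was above background in all 6 such pools and differed between the pool numbers by 0.086 ± 0.244 (SD, n = 5 time points). A loss of the 5p arm alone stays open. For miR-148b, absence could be expected to leave the level of the placental miRNAs, yet it read below the lowest of these in 4 of 6 such pools. That bound was set wrongly, and its reading was amended after the values were seen, because miR-132, never above background, read as low in 8 of the 11 pools. A shift of many probes between the measurements of the pools could not be decided either: over the 140 miRNAs never above background the mean correlation of the pool difference between time points was 0.064 (95% bootstrap interval 0.004 to 0.132). For miR-148b absence and a probe effect therefore cannot be told apart, for miR-590-5p a probe effect stays open, and so does a difference between the patients of the pools for both, which was not tested.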
